A study of Mus musculus with 12 samples.

How the data were processed

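Poly-A RNA of hearts of 12 female mice aged 12 weeks was sequenced as 61 bp single reads on a HiSeq 2500, in 3 groups (sham, MI+PBS and MI+Agrin) of 4 animals, 1 library each. The series' design text also lists another group of infarcted wild-type animals, which none of the samples used here carries. It states 4 animals per group, so p-values measure the spread between separate animals. Per the submitters' processing notes, cutadapt, STAR 2.4.2a, HTSeq and DESeq2 1.10.1 were used with the mm10 genome. The role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here.

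The deposited table holds 1 signal value per gene and library, normalized read counts per the file headers, rounded to 2 decimals. The values of 11 libraries are whole multiples of 1 step per library (99.98% to 100% of values within 0.0055 reads), so that whole reads could be recovered by dividing by that step. The step of sham replicate 2 lay too near 1 for this check, and tests on recovered reads leave that library out. The design had been fixed for either counts or normalized values, and the branch for normalized values was used. A further column of the table with 1 value per gene was not used here.

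Recovered totals ran from 20238511 to 22742027 reads. Genes with a mean of at least 5 normalized counts over the 12 libraries were kept, 14906 of 16218, and 1 was added before taking log2. All 12 libraries entered 1 linear model of group means in limma 3.58.1 (R 4.3.3) with an intensity trend. The 3 contrasts were tested with Benjamini-Hochberg adjustment at 0.05, and all adjusted p-values of genes come from this fit unless another tool is named.

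The design, the alternatives, the rule for named genes and the 41 lists (21 gene lists and 20 lists of cell type markers) were fixed before the data were examined. Lists with at least 4 measured members, 37 of them, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Fry asks whether the genes of a list move on balance one way, and does not compare the list with other genes. Mitochondrially encoded genes (0 measured), erythroid (3), lung epithelium (1) and thymus markers (1) had too few members. Members are also counted after adjustment over the list alone.

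Named genes were Agrn, Dag1, Yap1, Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1 and Postn in every comparison. In each comparison the 8 largest rises and 8 largest falls were added, among genes past the threshold with a mean of at least 50, no overlap between the groups and a named gene model. Up to 4 members per list with the smallest p were added, from which the examples were taken, and the 10 genes with the smallest p-values in both comparisons among those that moved back. Further members are named without values where 5 or fewer passed, and the 18 genes past in opposite directions, with Fos, Egr1 and the targets of glucocorticoids, were chosen after their values were seen. Results of some list members are not reported here.

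For the genes that moved back and for the overlap against sham, which share libraries between comparisons, 100 draws were simulated from permuted residuals with random signs, and for the former also without MI+PBS replicate 2. The shared group was also split 2 and 2 in 6 ways. The position of a library along the infarction axis is its projection on the difference of the sham and MI+PBS means over genes past the threshold, left out of its own axis for sham and MI+PBS libraries. MI+Agrin and MI+PBS libraries were compared with a two-sided exact permutation test over 70 assignments.

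The steps were tested on simulated counts with 50 genes changed at each of 4 fold sizes. The changed genes were drawn from those with a mean of at least 50, so the shares recovered do not cover lower genes. In MI+PBS against sham (14835 genes), limma recovered 26%, 64%, 94% and 100% of genes changed 1.25, 1.5, 2 and 4 fold, and called 6 of 14607 unchanged genes. In MI+Agrin against MI+PBS (14847 genes) the shares were 16%, 56%, 94% and 100% with 8 of 14620 unchanged genes called. In MI+Agrin against sham (14830 genes) they were 18%, 72%, 92% and 98% with 3 of 14603 called.

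Alternatives were other pseudocounts and filters, rescaling by TMM factors, limma without trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, only the 8 libraries of both groups, the replicate number as a block, quality weights, other thresholds and leaving out each library. Leaving out MI+PBS replicate 2 and MI+Agrin replicate 1 together was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

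Symbols were matched to GENCODE M21 for mm10 coordinates, and 135 of 135 named genes were found, 2 under another symbol. Exons of 12 of them share over 10% of their bases with another gene, so that these values are uncertain: Mt2 (73.47%), Nppa (61.5%), Fam84b (41.75%), Kcnj3 (31.08%), Fbn1, Gadd45a, Spp1, Aldh6a1, Dbp, Sox17, Dclre1b and Atcay. The gene overlapping Spp1 (18.75%) lies on the same strand, so that its value is uncertain under any strand setting. For the rest it lies on the opposite strand, and the uncertainty comes from the unknown strand setting. Chi3l3, Hspa1a and Hspa1b have near-identical relatives, between which reads could be divided.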

Results

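RNA was measured in heart tissue of 12 female mice in 3 groups of 4 animals. Sham animals had surgery without infarction. The other animals had a myocardial infarction after the left anterior descending artery was tied off for good, and the group names add either phosphate-buffered saline, the vehicle (MI+PBS), or agrin, a heparan sulfate proteoglycan of basement membranes (MI+Agrin). The labels place RNA extraction 2 weeks after infarction. The table gave normalized read counts for 16218 genes, of which 14906 had a mean of at least 5 and were tested. Between 20238511 and 22742027 reads per library were recovered for 11 libraries, and the normalized total of sham replicate 2 was 21695925. Between 15799 and 15898 genes were detected per library, and the 10 highest genes took 7.95% to 12.0% of the counts. Values below are log2 fold changes ± SE from 4 libraries per group, with limma p-values adjusted by the Benjamini-Hochberg method, unless another unit is named. All genes given as the largest rises or falls had 4 libraries of one group above all 4 of the other.

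The first principal component of the 12 libraries held 40.8% of the variance and the second 11.9%. MI+PBS replicate 2 lay farthest along the first, at 45.16 against 21.14 to 24.9 for the other MI+PBS libraries. MI+Agrin replicate 1 stood apart on the second, at -40.17.

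The comparison of MI+PBS with sham describes the infarcted heart without agrin. Most measured genes of scar matrix, dividing cells and macrophages were higher in the infarcted hearts, and most of mitochondrial energy metabolism and of ion channels were lower, although 0 of 37 lists passed with an estimated correlation. The largest rise was that of Spp1, which encodes the matricellular protein osteopontin, at 3.66 ± 0.39 (adjusted p = 3.72e-05). Collagen genes followed, with Col1a1 at 1.73 ± 0.18 (adjusted p = 3.36e-05) and Col3a1 at 1.30 ± 0.16 (adjusted p = 8.42e-05). The periostin gene Postn, a marker of activated fibroblasts, rose by 1.24 ± 0.28 (adjusted p = 0.00304).

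Among the other large rises were Sprr1a (3.66 ± 0.60), a stress-induced gene of injured cardiomyocytes, and Adam8 (3.25 ± 0.22), a membrane metalloprotease of leukocytes. Chi3l3 (3.08 ± 0.30) and Arg1 (3.05 ± 0.39), both on the fixed list of macrophage markers, rose with them, as did Sh2d5 (3.16 ± 0.45). The heme oxygenase gene Hmox1 rose by 2.98 ± 0.13 (adjusted p = 1.53e-07) and the metallothionein gene Mt2 by 2.98 ± 0.21 (adjusted p = 4.55e-06). The largest falls were those of Retnla (-2.39 ± 0.45), a resistin-like gene of macrophages, Ky (-2.07 ± 0.21), Pla2g2d (-1.92 ± 0.24) and Akap5 (-1.89 ± 0.19), an anchoring protein of protein kinase A. Snai3 (-1.82 ± 0.25), Lgi1 (-1.75 ± 0.32), Cilp2 (-1.73 ± 0.37) and the chloride channel gene Clcn1 (-1.68 ± 0.20) followed. The adjusted p-values of these 8 falls ran from 3.02e-05 to 0.00245.

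Agrn, which encodes agrin itself, did not pass the test (-0.24 ± 0.10, adjusted p = 0.0783), nor did Dag1, the gene of the agrin receptor dystroglycan (-0.17 ± 0.06, adjusted p = 0.0524). Yap1, a transcriptional coactivator of the Hippo pathway, fell by 0.33 ± 0.08 on the log2 scale (adjusted p = 0.00391). The natriuretic peptide gene Nppb rose by 1.88 ± 0.39 (adjusted p = 0.00192), whereas Nppa (0.72 ± 0.33, adjusted p = 0.0979) did not pass. The myosin heavy chain genes Myh6 (-0.51 ± 0.21, adjusted p = 0.0683) and Myh7 (-0.31 ± 0.18, adjusted p = 0.179) did not pass either. In mm10, Agrn lies on chromosome 4 from 156165290 to 156197488, Dag1 on chromosome 9 from 108204634 to 108263958, Yap1 on chromosome 9 from 7931999 to 8004596 and Spp1 on chromosome 5 from 104435118 to 104441050.

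Of the 36 measured genes of fibrillar collagens and matrix, 31 rose, 1 (Fmod) fell and 4 did not pass, with the same counts adjusted over the list alone and a median of 0.97. Thbs1 (2.26 ± 0.18), which encodes the matricellular protein thrombospondin, Col5a1 (1.53 ± 0.14) and Col6a3 (0.98 ± 0.10) were among them. Of the 22 genes of collagen cross-linking and processing, 19 rose and 3 did not pass (21 rose adjusted over the list alone), including the lysyl oxidase gene Lox (2.32 ± 0.20) and the procollagen C-proteinase gene Bmp1 (0.96 ± 0.07). Of 22 myofibroblast and TGF-beta genes, 17 rose and 5 did not pass, the same adjusted over the list alone, with Adam12 (1.81 ± 0.19) among them. Of 23 matrix proteases and inhibitors, 14 rose, 1 (Adamts5) fell and 8 did not pass, also when adjusted over the list alone, with Timp1 at 2.72 ± 0.18 and Adamts4 at 2.50 ± 0.22. All 4 lists passed camera upward, with adjusted p-values from 1.33e-11 to 3.48e-05. None held with an estimated correlation (adjusted p = 0.243 with an estimated correlation for each). Lox was highest in MI+PBS replicate 2, at 5463.9 normalized counts against 3550 to 3744.5 in the other MI+PBS libraries.

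Dividing-cell genes were the list with the smallest camera p. Of 32 mitotic and S-phase genes, 30 rose and 2 did not pass (30 rose and 1 fell adjusted over the list alone), with a median of 1.67 (camera adjusted p = 1.46e-13, and adjusted p = 0.247 with an estimated correlation). Ccnb1 (2.16 ± 0.23), the mitotic cyclin, Hmmr (2.05 ± 0.22) and Cdc20 (1.75 ± 0.18), an activator of the anaphase-promoting complex, were among them. Rrm2, a ribonucleotide reductase subunit, stood at 502.45 normalized counts in MI+PBS replicate 2 and at 262.52 to 280.85 in the other MI+PBS libraries.

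Most macrophage and neutrophil markers rose as well. Of 25 macrophage markers, 22 rose and 3 did not pass, also when adjusted over the list alone (median 1.18). Besides Spp1 and Chi3l3 they included Mrc1 (0.96 ± 0.08), the mannose receptor. Of 8 neutrophil markers, 6 rose and 2 did not pass, the same adjusted over the list alone, including the granulocyte colony-stimulating factor receptor gene Csf3r (1.35 ± 0.14) and the neutrophil collagenase gene Mmp8 (2.82 ± 0.46). Of 31 cytokines and chemokines, 17 rose and 14 did not pass (19 rose and 1 fell adjusted over the list alone), with the interleukin receptor antagonist gene Il1rn at 2.45 ± 0.29 and Il11 at 2.47 ± 0.30. The camera adjusted p-values of these lists were 3.94e-09, 0.007 and 7.85e-06. With an estimated correlation they were lost (adjusted p = 0.243, 0.247 and 0.243 with an estimated correlation). MI+PBS replicate 2 held the highest Il1rn value, 344.34 normalized counts against 123.2 to 160.35 in the other MI+PBS libraries.

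Of 20 fetal and stress genes of cardiomyocytes, 15 rose and 5 did not pass, also when adjusted over the list alone, with a median of 0.77. The alpha-actinin gene Actn1 (1.25 ± 0.10) and the LIM-domain gene Fhl1 (1.19 ± 0.12) were among them. Of 19 genes of the unfolded protein response, 15 rose and 4 did not pass, the same adjusted over the list alone, including the stress-induced transcription factor gene Atf3 (2.28 ± 0.14) and the asparagine synthetase gene Asns (1.41 ± 0.14). Of 22 immediate early and heat shock genes, 11 rose and 11 did not pass (12 rose and 1 fell adjusted over the list alone), with Fosb at 2.09 ± 0.27. The camera adjusted p-values were 4.76e-06, 1.5e-07 and 0.007, and all were lost with an estimated correlation (adjusted p = 0.243, 0.243 and 0.262 with an estimated correlation).

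Most genes of energy supply fell. Of 28 genes of oxidative phosphorylation, 27 fell and 1 did not pass (28 fell adjusted over the list alone), with a median of -0.48, including the complex II subunit gene Sdhd (-0.44 ± 0.06) and the complex I subunit gene Ndufa9 (-0.48 ± 0.07). Of 27 genes of fatty acid oxidation, 21 fell, 1 (Pdk4) rose and 5 did not pass (23 fell adjusted over the list alone), including Acadm (-0.67 ± 0.10), the medium-chain acyl-CoA dehydrogenase, and Acads (-0.55 ± 0.09). Of 17 genes of branched-chain amino acid and ketone use, 16 fell and 1 did not pass (17 fell adjusted over the list alone), including Ivd (-0.73 ± 0.09) and Mut (-0.59 ± 0.07). Their camera adjusted p-values were 1.33e-11, 1.16e-06 and 9.16e-09, and none held with an estimated correlation (adjusted p = 0.247, 0.429 and 0.243 with an estimated correlation). Ndufa9 was lowest in MI+PBS replicate 2, at 7420.3 normalized counts against 8655.9 to 8824.2 in the other MI+PBS libraries.

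Of 22 genes of calcium handling and ion channels, 15 fell and 7 did not pass (19 fell adjusted over the list alone), with the potassium channel genes Kcnj3 (-0.85 ± 0.11) and Kcnd2 (-0.79 ± 0.11) among them. Of 22 adult sarcomere genes, 9 fell and 13 did not pass, also when adjusted over the list alone, with the titin-cap gene Tcap at -0.99 ± 0.11 and the nebulette gene Nebl at -0.47 ± 0.06. Of 25 genes of agrin receptors and the dystrophin-glycoprotein complex, 11 fell, 1 (Sntb1) rose and 13 did not pass (13 fell adjusted over the list alone). Lrp4, an agrin co-receptor at the neuromuscular junction, fell by 0.45 ± 0.07 and the sarcospan gene Sspn by 0.68 ± 0.11 on the log2 scale. Camera adjusted p-values were 2.59e-06, 0.00052 and 0.00918, and the calls were lost with an estimated correlation (adjusted p = 0.243, 0.429 and 0.243 with an estimated correlation).

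The other lists did not pass camera in this comparison. Of 28 angiogenic factors and receptors, 7 rose and 9 fell (8 and 10 adjusted over the list alone), with Angptl4 at 2.29 ± 0.25 and Kdr, the main endothelial receptor of vascular endothelial growth factor, at -0.66 ± 0.09. Of 22 YAP and TEAD targets, 11 rose and 2 (Gadd45a and Dock5) fell, also when adjusted over the list alone, with Gadd45a at -0.97 ± 0.11. Of 24 glycolysis and hypoxia genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone), including the insulin-responsive glucose transporter gene Slc2a4 at -0.66 ± 0.06. Of 17 clock genes, 7 fell and 1 (Nfil3) rose, the same adjusted over the list alone, with Dbp at -1.44 ± 0.27 and Nr1d1 at -0.77 ± 0.14. Of 26 interferon-stimulated genes, 3 (Gbp2, Gbp3 and Iigp1) fell, as when adjusted over the list alone.

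Among markers of other cell types, 5 of 15 endothelial genes rose, with Esam at 0.34 ± 0.05, and 5 of 12 pericyte and smooth muscle genes fell while 1 (Cspg4) rose. Kcnj8, the pore subunit of an ATP-sensitive potassium channel of pericytes, fell by 0.89 ± 0.07 on the log2 scale (adjusted p = 8.45e-06). Of 12 resting fibroblast markers, 1 (Cd248) rose and 3 (Tcf21, Gsn and Smoc2) fell, and of 6 lymphatic endothelial markers 2 rose and 2 fell. Of 6 platelet markers 1 (Pf4) rose. Adjusted over the list alone, the counts were the same for these lists except the lymphatic one, with 3 rises. Of 11 adipocyte markers, 3 fell (2 adjusted over the list alone). At most 3 members changed, also when adjusted over the list alone, in each of the lists of T and NK cells, B and plasma cells, mast cells, epicardium, atrial cardiomyocytes, conduction system, cartilage and valve, Schwann cells and skeletal muscle.

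Of the 14906 genes tested, 6616 passed, 3371 higher and 3245 lower in MI+PBS than in sham, and 1026 of them differed by at least 1 log2 unit. The groups did not overlap in 41.9% of genes, where chance gives 2.86%. Camera passed 17 of 37 lists tested (11 up and 6 down) and fry passed 23, but camera with an estimated correlation passed 0.

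**Figure D1:**
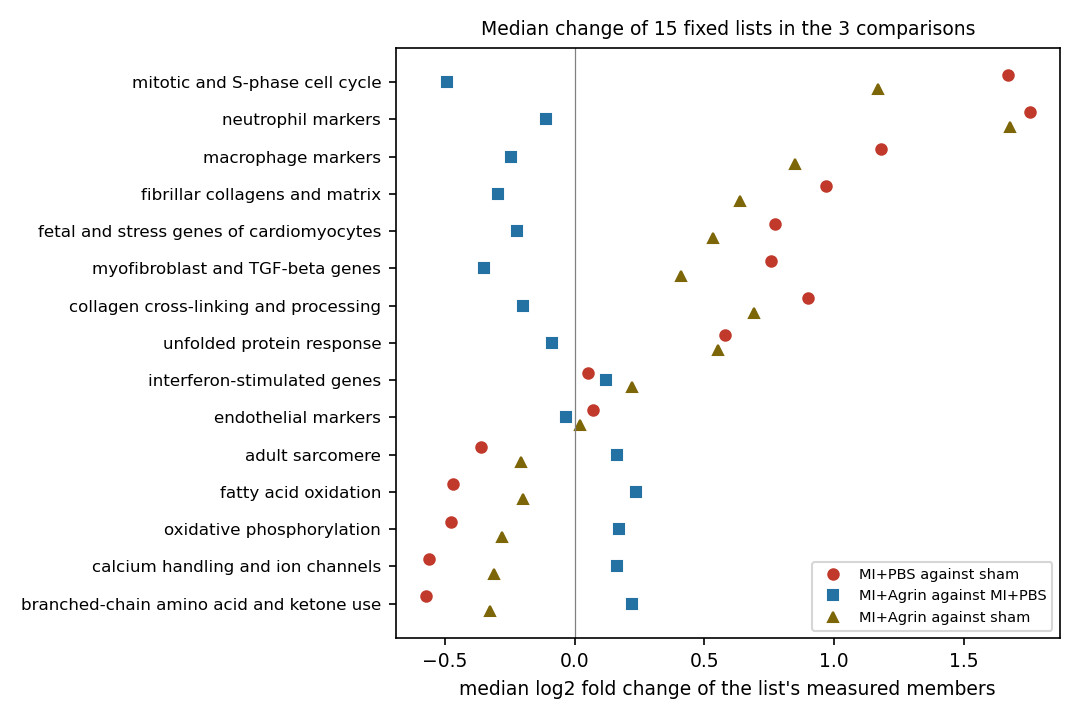
Median log2 fold change of the measured members of 15 fixed gene lists (x axis, log2 units) in the 3 comparisons, 1 point per list and comparison. The cell cycle list lies at 1.67 in MI+PBS against sham, at -0.49 in MI+Agrin against MI+PBS and at 1.17 in MI+Agrin against sham.

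The comparison of MI+Agrin with MI+PBS addresses what agrin adds to the infarcted heart. Nr4a1, an orphan nuclear receptor induced within minutes of many stimuli, fell by 1.70 ± 0.23 on the log2 scale (adjusted p = 0.00306), and Per1, a repressor of the circadian clock, by 1.45 ± 0.22 (adjusted p = 0.00464). Kdr and Kcnj8, both lower after infarction, were higher with agrin than with PBS. Matrix, cell cycle and metabolic lists passed camera in the direction of sham, but 0 of 37 lists passed with an estimated correlation and 0 by fry, and few members of these lists passed singly.

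The largest falls also held Tmem252 (-2.0001 ± 0.29), Ddit4 (-1.57 ± 0.20), a stress-induced inhibitor of mTOR signaling, and Errfi1 (-1.34 ± 0.14), a feedback inhibitor of epidermal growth factor receptors. Runx3 (-1.42 ± 0.23), a lymphocyte transcription factor, Rgcc (-1.25 ± 0.17) and the Src-like adapter gene Sla (-1.22 ± 0.21) were the other ones, and adjusted p-values of these 6 ran from 0.000437 to 0.0105. The largest rises were Rassf9 (1.47 ± 0.21), G0s2 (1.44 ± 0.20), an inhibitor of adipose triglyceride lipase, Fam84b (1.18 ± 0.11), Fam102a (1.061 ± 0.09) and the adenosine receptor gene Adora2a (1.03 ± 0.11). Tnfsf10 (0.98 ± 0.12), which encodes the death receptor ligand TRAIL, Myct1 (0.86 ± 0.10) and Myrip (0.85 ± 0.17) followed, with adjusted p-values from 0.000204 to 0.0286 over the 8 rises. Exons of Fam84b overlap those of an antisense gene over 41.75% of their bases, so that its value is uncertain. Nr4a1 lies on chromosome 15 from 101254269 to 101274795, Per1 on chromosome 11 from 69095217 to 69109960 and Kdr on chromosome 5 from 75932827 to 75978458.

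**Figure D2:**
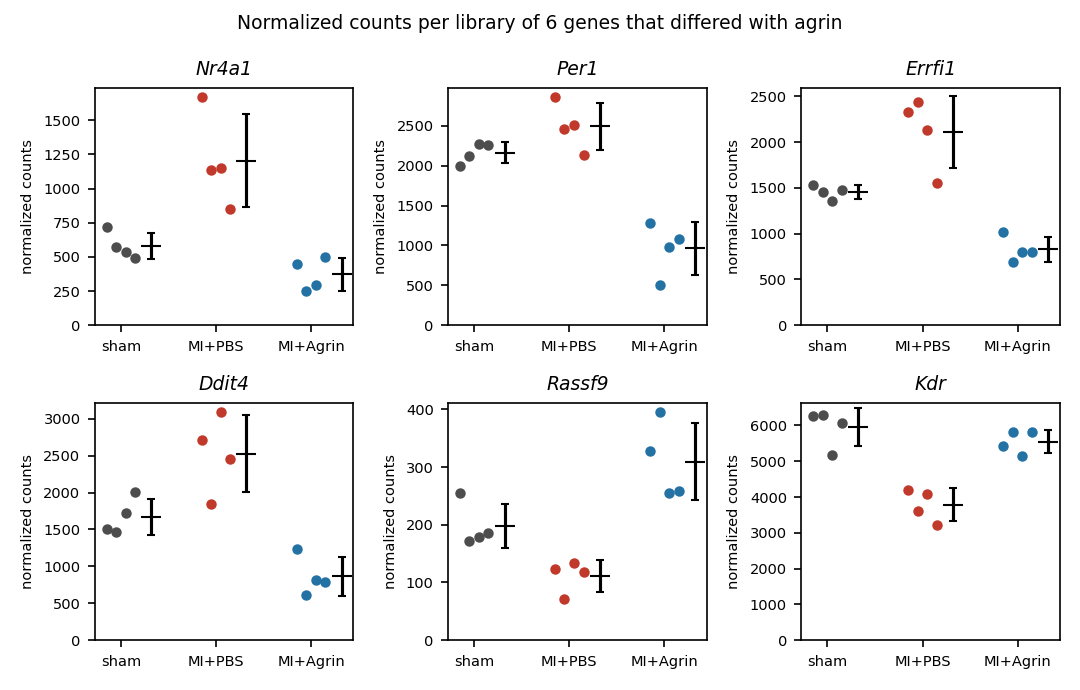
Normalized counts (y axis) of 6 genes in each of the 12 libraries, 4 points per group, with the group mean and its SD as a bar. Nr4a1 lies at 852.55 to 1669.6 in MI+PBS and at 247.75 to 501.3 in MI+Agrin.

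None of the 10 genes fixed for every comparison passed. Agrn did not differ (adjusted p = 0.999, SE 0.10), at a mean of 2535.7 ± 250.2 (SD, n = 4) normalized counts with PBS and 2546.3 ± 393.8 (SD, n = 4) with agrin. Dag1 (0.13 ± 0.06, adjusted p = 0.3), Yap1 (0.12 ± 0.08, adjusted p = 0.405) and Nppb (-0.95 ± 0.39, adjusted p = 0.218) did not pass. Col1a1 (-0.29 ± 0.18), Col3a1 (-0.30 ± 0.16), Postn (-0.40 ± 0.28), Myh6 (0.26 ± 0.21), Myh7 (0.23 ± 0.18) and Nppa (-0.17 ± 0.33) had adjusted p-values from 0.33 to 0.816. Myh7 was highest in MI+Agrin replicate 1, at 55836 normalized counts against 33311 to 36352 in the other MI+Agrin libraries.

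Of the 22 immediate early and heat shock genes, 4 fell and 18 did not pass (2 rose and 5 fell adjusted over the list alone). The 4 were Nr4a1, Atf3 (-1.07 ± 0.14, adjusted p = 0.00224), Fosb (-1.29 ± 0.27, adjusted p = 0.0356) and Btg2 (-0.53 ± 0.12, adjusted p = 0.0493). Fos (-0.27 ± 0.25, adjusted p = 0.574) and Egr1 (0.05 ± 0.19, adjusted p = 0.908) did not pass. The list itself did not pass camera (adjusted p = 0.294). Of 17 clock genes, Per1 fell, Nr1d1 rose (0.70 ± 0.14, adjusted p = 0.0265) and 15 did not pass (3 rose and 1 fell adjusted over the list alone). Of 19 genes of the unfolded protein response, 2 fell, Atf3 and Chac1 (-0.63 ± 0.13), and 17 did not pass (2 rose and 3 fell adjusted over the list alone).

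Of 27 fatty acid oxidation genes and 28 oxidative phosphorylation genes, 0 rose and 0 fell by limma over all genes, and 0 adjusted over the list alone. Their medians were 0.24 and 0.17. Acadm (0.31 ± 0.10, adjusted p = 0.148), Ppara (0.37 ± 0.12, adjusted p = 0.136) and Sdha (0.25 ± 0.08, adjusted p = 0.148) had some of the smallest p-values. Of 17 genes of branched-chain amino acid and ketone use, 1 rose, Aldh6a1 (0.45 ± 0.10), and 16 did not pass (12 rose adjusted over the list alone), with a median of 0.22. Camera passed the 3 lists upward (adjusted p = 1.34e-07 for fatty acid oxidation and 1.75e-07 for each of the others), and none held with an estimated correlation (adjusted p = 0.448 with an estimated correlation for each). Sdha was lowest in MI+PBS replicate 2, at 23825 normalized counts against 28878 to 29430 in the other MI+PBS libraries, and Acadm highest in MI+Agrin replicate 1, at 26714 against 21113 to 23312 in the other MI+Agrin libraries. The medians of the 3 lists were 0.21, 0.188 and 0.212 without MI+Agrin replicate 1, which also held the highest Ucp1 and Plin1 values, and 0.14, 0.106 and 0.159 without MI+PBS replicate 2.

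Of 22 adult sarcomere genes, Tcap rose (0.49 ± 0.11) and 21 did not pass, and of 22 calcium handling and ion channel genes, Kcnj2 rose (0.85 ± 0.16) and 21 did not pass. Of 24 glycolysis and hypoxia genes, Slc2a4 rose (0.33 ± 0.06) and 23 did not pass (3 rose adjusted over the list alone, where the counts of the former lists stayed at 1). Camera passed the 3 lists upward with adjusted p-values of 0.00716, 0.00502 and 0.0309, which were lost with an estimated correlation (adjusted p = 0.631, 0.448 and 0.448 with an estimated correlation). Of 20 fetal and stress genes, Xirp1 fell (-0.39 ± 0.08) and 19 did not pass (3 fell adjusted over the list alone). This list passed downward (adjusted p = 0.00192, and adjusted p = 0.448 with an estimated correlation).

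Of 36 matrix genes, Thbs1 fell (-1.14 ± 0.18, adjusted p = 0.00756) and 35 did not pass (2 fell adjusted over the list alone). Of 22 cross-linking genes 0 changed by limma, also when adjusted over the list alone, and of 22 myofibroblast genes 0 changed (5 fell adjusted over the list alone), with Cnn2 at -0.37 ± 0.11 (adjusted p = 0.107). Of 32 cell cycle genes 0 changed and 0 adjusted over the list alone, at a median of -0.49, with Rrm2 at -0.66 ± 0.22 (adjusted p = 0.154) and Pcna at -0.37 ± 0.12 (adjusted p = 0.136). Of 25 macrophage markers 0 changed, also when adjusted over the list alone. Camera passed these 5 lists downward (adjusted p = 1.34e-07, 0.000408, 5.21e-05, 3.32e-08 and 0.0134), and none held with an estimated correlation (adjusted p = 0.448 for the matrix, myofibroblast and cell cycle lists, 0.566 for cross-linking and 0.631 for macrophages, each with an estimated correlation). Fry passed 0 of 37 lists in this comparison. Part of the fall rests on MI+PBS replicate 2, without which the medians were -0.216 for matrix (-0.297 with it), -0.133 for cross-linking (-0.198), -0.214 for myofibroblasts (-0.352), -0.316 for the cell cycle (-0.493) and -0.204 for macrophages (-0.247). Without MI+Agrin replicate 1 they were -0.194, -0.153, -0.281, -0.407 and -0.095.

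Vascular genes changed singly. Kdr rose by 0.56 ± 0.09 (adjusted p = 0.00756) and Thbs1, which is also an angiogenesis inhibitor, fell among 28 angiogenic genes, of which 26 did not pass (2 rose and 2 fell adjusted over the list alone). Of 15 endothelial markers Esam fell (-0.32 ± 0.05, adjusted p = 0.00855) and 14 did not pass (2 fell adjusted over the list alone), and of 12 pericyte and smooth muscle markers Kcnj8 rose (0.56 ± 0.07, adjusted p = 0.00165) and 11 did not pass (1 rose and 1 fell adjusted over the list alone). Of 23 matrix proteases and inhibitors, Adamts5 rose (0.47 ± 0.10) and 22 did not pass (1 rose and 3 fell adjusted over the list alone). Of 25 genes of agrin receptors and the dystrophin-glycoprotein complex, Dtna, which encodes dystrobrevin, rose (0.32 ± 0.06, adjusted p = 0.0179) and 24 did not pass (2 rose adjusted over the list alone). These 5 lists did not pass camera.

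The adipocyte list passed camera upward (median 0.83, adjusted p = 0.000408, and adjusted p = 0.448 with an estimated correlation), with 0 of 11 members past limma, also when adjusted over the list alone. MI+Agrin replicate 1 held 829 normalized counts of Ucp1, the uncoupling protein of brown fat, against 4.7 to 39.42 in the other MI+Agrin libraries. In it Plin1 stood at 401.32 against 98.71 to 181.15, and of the mesothelial and atrial markers Upk3b stood at 1698.5 against 335.6 to 894.5, Msln at 1234.4 against 411.61 to 725.55 and Myl7 at 16708 against 4833.4 to 9599.2. Without it the list medians were 0.57 for adipocytes, 0.095 for mesothelium and epicardium (0.406 with it) and 0.078 for atrial cardiomyocytes (0.339 with it). No member changed by limma among YAP and TEAD targets, cytokines, interferon-stimulated genes, neutrophils, T and NK cells, B and plasma cells, mast cells, lymphatic endothelium, resting fibroblasts, epicardium, atrial cardiomyocytes, conduction system, cartilage and valve, platelets, Schwann cells and skeletal muscle, and none of these lists passed camera. Adjusted over the list alone, 1 atrial and 1 lymphatic marker rose and the others stayed at 0. At an unadjusted p under 0.05, 2802 of all genes passed.

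In total 245 genes passed, 112 higher and 133 lower with agrin, and 31 differed by at least 1 log2 unit. The groups did not overlap in 9.04% of genes, where chance gives 2.86%. Camera passed 13 of 37 lists (7 up and 6 down), and 0 with an estimated correlation. The count of genes fell to 145 without MI+PBS replicate 2, to 137 without MI+Agrin replicate 3 and to 93 with only the 8 libraries of both groups, while DESeq2 on recovered reads gave 602. Calls of Tcap, Btg2, Aldh6a1, Chac1, Xirp1, Adamts5, Fosb, Myrip, Nr1d1, Kcnj2, Dtna and Slc2a4 were each lost when 1 or more single libraries were left out, with adjusted p-values of up to 0.221 over all alternatives.

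Whether infarction genes moved back toward sham was asked over the 6616 genes past in MI+PBS against sham. In 5898 of them (89.15%) the agrin estimate had the opposite sign. The 10 genes with the smallest p-values in both comparisons were Arrdc3, Atp8b1, Adora2a, Kcnj8, Mgat4a, Sema7a, Tnfsf10, Kcne4, Atf3 and Tiparp. Atf3 rose by 2.28 ± 0.14 with infarction and fell by 1.07 ± 0.14 with agrin, and Tnfsf10 fell by 1.22 ± 0.12 and rose by 0.98 ± 0.12. Kcne4, a potassium channel subunit gene, rose by 1.15 ± 0.13 and fell by 0.98 ± 0.13 in the same order, and Atp8b1, a phospholipid flippase gene, rose by 0.97 ± 0.08 and fell by 0.67 ± 0.08 on the log2 scale.

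Of the 245 agrin genes, 202 were also infarction genes and 200 of these had opposite signs, where independent lists would share 54.46. In MI+Agrin against sham, 140 of the 202 did not pass. Both comparisons use the MI+PBS libraries, which alone gives opposite signs. With agrin simulated to have no effect, the mean was 58.69% (27.85% to 85.28% over 100 draws). The covariance of both estimates was -0.0938 against a simulated mean of -0.0314 (-0.1005 to 0.02284 over the draws, 3 of 100 as large as observed), a difference of -0.0623 from that mean, and their correlation across genes, which are not independent replicates, was -0.585 against -0.211. With the MI+PBS libraries split so that each comparison used its own 2, the share was 81.5% on average over 6 ways (75.62% to 89.2%).

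Each library was then placed along the infarction axis, from 0 at the sham mean to 1 at the MI+PBS mean. MI+PBS libraries lay at 0.933 ± 0.203 (SD, n = 4), MI+Agrin libraries at 0.712 ± 0.133 (SD, n = 4) and sham libraries at 0.056 ± 0.128 (SD, n = 4). The difference of -0.22 between agrin and PBS did not pass a two-sided exact permutation test (p = 0.114, smallest possible 0.0286). MI+PBS replicate 2 lay at 1.237 and the other MI+PBS libraries at 0.813 to 0.857, and without it the difference was -0.118. MI+Agrin libraries lay at 0.567, 0.634, 0.808 and 0.841.

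**Figure D3:**
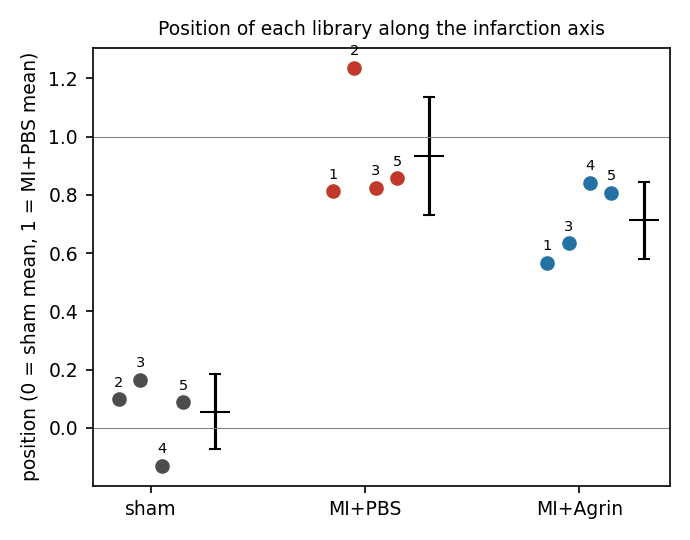
Position of each of the 12 libraries along the infarction axis (y axis, no unit; 0 is the sham mean and 1 the MI+PBS mean), labelled by replicate number, with group mean and SD. MI+Agrin libraries span 0.567 to 0.841 and MI+PBS libraries 0.813 to 1.237.

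The comparison of MI+Agrin with sham describes the infarcted heart with agrin. Most measured matrix, macrophage and dividing-cell genes were higher and most oxidative phosphorylation genes lower than in sham, as in the PBS-treated hearts, although 0 of 37 lists passed with an estimated correlation. Spp1 rose by 3.25 ± 0.39 (adjusted p = 0.000272), Hmox1 by 2.82 ± 0.13 (adjusted p = 2.99e-07) and Col1a1 by 1.44 ± 0.18 (adjusted p = 0.000329). Zbtb16, a zinc finger gene induced by glucocorticoids, rose by 2.69 ± 0.25 (adjusted p = 7.39e-05). Per1 fell (adjusted p = 0.00158), from 1997.3 to 2268.7 normalized counts in the sham libraries to 504.39 to 1276.9 with agrin.

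The other large rises were Adam8 (2.75 ± 0.22), Chi3l3 (2.69 ± 0.30), the lipocalin gene Lcn2 (2.59 ± 0.28), Mt2 (2.56 ± 0.21) and the monocyte chemoattractant gene Ccl7 (2.47 ± 0.36). The largest falls were Atcay (-2.05 ± 0.34), Akap5 (-1.87 ± 0.19), Lgi1 (-1.65 ± 0.32), Ky (-1.62 ± 0.21), Fbxo44 (-1.56 ± 0.37), Retnla (-1.56 ± 0.45), Itgb6 (-1.53 ± 0.15) and Clec3a (-1.47 ± 0.31), with adjusted p-values from 0.000114 to 0.022. Col3a1 rose by 0.996 ± 0.16 (adjusted p = 0.00116) and Postn by 0.84 ± 0.28 (adjusted p = 0.0377). Agrn (-0.24 ± 0.10, adjusted p = 0.101), Dag1 (-0.04 ± 0.06, adjusted p = 0.702), Yap1 (-0.21 ± 0.08, adjusted p = 0.0579) and Nppb (0.92 ± 0.39, adjusted p = 0.0932) did not pass, nor did Nppa (0.55 ± 0.33), Myh6 (-0.25 ± 0.21) and Myh7 (-0.08 ± 0.18). Whether Nppb differs between both infarcted groups was tested above and did not pass.

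Of 36 matrix genes 23 rose, 1 (Fmod) fell and 12 did not pass (27 rose and 1 fell adjusted over the list alone), with Col5a1 at 1.24 ± 0.14. Of 22 cross-linking genes 19 rose and 3 did not pass (20 rose adjusted over the list alone), with Bmp1 at 0.77 ± 0.07. Of 22 myofibroblast genes 12 rose and 10 did not pass (14 rose adjusted over the list alone), with Runx1 at 1.26 ± 0.16, and of 23 matrix proteases and inhibitors 11 rose and 12 did not pass, also when adjusted over the list alone, with Timp1 at 2.14 ± 0.18. Of 32 cell cycle genes 27 rose and 5 did not pass (28 rose adjusted over the list alone), with Hmmr at 1.54 ± 0.22 and Cdc20 at 1.42 ± 0.18. Camera passed these 5 lists upward with adjusted p-values from 2.5e-12 to 1.08e-05, and none held with an estimated correlation (adjusted p = 0.293 to 0.299 with an estimated correlation).

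Of 25 macrophage markers 20 rose and 5 did not pass (22 rose adjusted over the list alone), with Mrc1 at 0.81 ± 0.08. Of 8 neutrophil markers 5 rose and 3 did not pass (6 rose adjusted over the list alone), with Csf3r at 1.28 ± 0.14, and of 31 cytokines and chemokines 20 rose and 11 did not pass (21 rose adjusted over the list alone). Of 20 fetal and stress genes 11 rose and 9 did not pass (12 rose adjusted over the list alone), with Actn1 at 0.88 ± 0.10. Of 19 genes of the unfolded protein response 15 rose and 4 did not pass (17 rose adjusted over the list alone), with Atf3 at 1.21 ± 0.14. Of 22 immediate early and heat shock genes 6 rose, 1 (Nr4a1) fell and 15 did not pass (9 rose and 1 fell adjusted over the list alone). All 6 lists passed camera upward (adjusted p from 5.1e-10 to 0.0089), and none held with an estimated correlation (adjusted p = 0.293 to 0.299 with an estimated correlation).

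Of 28 oxidative phosphorylation genes 22 fell and 6 did not pass (27 fell adjusted over the list alone), with Sdhd at -0.35 ± 0.06. Of 27 fatty acid oxidation genes 6 fell, 1 (Pdk4) rose and 20 did not pass (8 fell and 1 rose adjusted over the list alone). Of 17 genes of branched-chain amino acid and ketone use 11 fell and 6 did not pass (12 fell adjusted over the list alone), with the propionyl-CoA carboxylase gene Pcca at -0.37 ± 0.08. Of 22 calcium handling and ion channel genes 11 fell and 11 did not pass (12 fell adjusted over the list alone), with Kcnj3 at -0.72 ± 0.11. Of 22 adult sarcomere genes 7 fell and 15 did not pass, also when adjusted over the list alone, with Nebl at -0.39 ± 0.06. Of 25 genes of agrin receptors and the dystrophin-glycoprotein complex 5 fell, 1 rose and 19 did not pass, the same adjusted over the list alone, with the utrophin gene Utrn at -0.25 ± 0.05 and Sspn at -0.51 ± 0.11. Camera passed these 6 lists downward (adjusted p from 5.81e-10 to 0.0329), and the calls were lost with an estimated correlation (adjusted p = 0.299 to 0.686 with an estimated correlation).

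Camera also passed the pericyte and smooth muscle list downward (5 fell and 1 rose of 12, against 6 and 1 adjusted over the list alone, adjusted p = 0.0492) and the platelet list upward (2 of 6 rose, 3 adjusted over the list alone, adjusted p = 0.0415). Both were lost (adjusted p = 0.306 and 0.437 with an estimated correlation). Lists that did not pass included YAP and TEAD targets (9 rose and 2 fell of 22), glycolysis and hypoxia (5 rose and 8 fell of 24), angiogenic genes (5 rose and 6 fell of 28), clock genes (Per1 fell, of 17) and interferon-stimulated genes (Iigp1 fell, of 26). Adjusted over the list alone these counts were the same except for the angiogenic list, with 6 rises and 7 falls. Gadd45a stood at -0.78 ± 0.11, Ndrg1 at 0.50 ± 0.07 and Angptl4 at 1.96 ± 0.25. Of 11 adipocyte markers Thrsp fell, and in each of the other marker lists no more than 4 members changed.

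In this comparison 4261 genes passed, 2290 higher and 1971 lower, with 598 of at least 1 log2 unit. The groups did not overlap in 32.4% of genes, where chance gives 2.86%. Camera passed 19 of 37 lists (12 up and 7 down) and fry 17, and camera with an estimated correlation passed 0. The call of Postn was lost without sham replicate 3 or 4 and without MI+Agrin replicate 3, 4 or 5, and that of Retnla without sham replicate 2, with adjusted p-values of up to 0.114 and 0.0709 over all alternatives.

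In both comparisons against sham, 3719 genes passed in the same direction, 2045 higher and 1674 lower, where independent lists would share 947. The comparisons share their sham libraries. With both groups simulated as unchanged, at most 6 genes were shared in 100 draws, and the covariance of both estimates was 0.221 against 0.0283 simulated, a difference of 0.193. Their correlation across genes was 0.862 against 0.49. These simulated draws take the infarction effect out of both groups, so they do not test an overlap beyond that effect. With sham libraries split 2 and 2, 1873 genes were shared on average (1410 to 2273), where independent lists would share 379.8. Over the infarction genes, estimates with agrin had a slope of 0.712 on those with PBS. These genes were chosen by their PBS estimates, which alone can lower the slope. No value without an agrin effect was simulated for it, so it does not measure a smaller response.

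A further 18 genes passed in both comparisons with opposite signs, 12 higher with PBS and lower with agrin than sham and 6 the reverse. All 18 also passed in MI+Agrin against MI+PBS. That estimate is the difference of those against sham and has the same SE. Changes of opposite sign add up in it, so this is no separate support. Nr4a1 stood at 1.03 ± 0.23 with PBS and at -0.68 ± 0.23 with agrin, and Irs2, an adapter of insulin receptors, at 0.69 ± 0.12 and -0.40 ± 0.12. S1pr1, a sphingosine phosphate receptor of endothelium, stood at 0.41 ± 0.08 and -0.41 ± 0.08, and Sik1, a salt-inducible kinase, at 0.32 ± 0.12 and -0.84 ± 0.12. Fam102a (-0.61 ± 0.09 and 0.45 ± 0.09) and Tob1 (-0.41 ± 0.08 and 0.27 ± 0.08) went the other way.

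**Figure D4:**
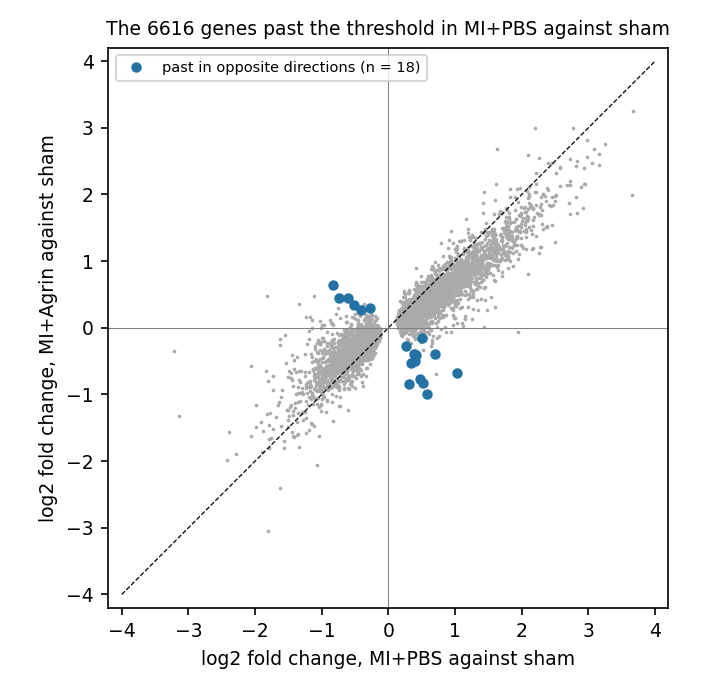
Log2 fold change against sham with agrin (y axis) and with PBS (x axis) for the 6616 genes past the threshold in MI+PBS against sham, 1 point per gene; the dashed line marks equal change. The 18 colored points passed in opposite directions.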

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

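The test of the MI+PBS data without replicate 2 was planned, whereas its simulated draws without that library and the tests of a fixed share of the response, of other assignments of the libraries, of the hour, of glucocorticoids and of handling were chosen only after the results were seen. Of 393 groups of 4 values looked at, 30 had 1 library far from the other libraries of its group, where chance gives about 1 in 20 (19.6). MI+PBS replicate 2 was that library in 9, MI+PBS replicate 1 and MI+Agrin replicate 1 in 4 each.

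MI+PBS replicate 2 lay at 1.237 along the infarction axis against 0.813 to 0.857 in the other MI+PBS libraries, and at 45.16 on the first principal component. In it Rrm2 (502.45 normalized counts), Lox (5463.9), Il1rn (344.34) and Ccl7 (706.14) were higher than in the rest of its group. Ndufa9 (7420.3), Sdha (23825) and the share of the 10 highest genes (7.95%) were lower. In MI+PBS replicate 1, Fosb (116.62), Atcay (88.43) and Sdhd (9918.3) were high and Ndrg1 (1740.5) was low. In MI+PBS replicate 3, Yap1 (3395.2) and Myct1 (382.41) were high and Pla2g2d (18.6) was low.

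In MI+Agrin replicate 1, Ucp1 (829 normalized counts), Myh7 (55836) and Kcnj8 (794.54) were high and Csf3r (284.78) was low, each far from the rest of its group. The total of MI+Agrin replicate 3 (21710000 normalized counts) was high, as was Sspn (6304.4) in MI+Agrin replicate 5. Among sham libraries, replicate 2 was high in Retnla (206.2) and Rassf9 (254.72), replicate 3 was high in Sh2d5 (19.16) and Pcna (370.5), and replicate 4 was high in Myh6 (711980). Low values were those of Ndufs1 in sham replicate 3 (20803), Kcnj2 in sham replicate 4 (1752) and Arrdc3 in sham replicate 5 (1719).

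The 18 genes past in opposite directions against sham also passed between the infarcted groups by limma, where both changes add up, so this is no separate support. With agrin, Nr4a1 (-1.70), Ddit4 (-1.57), Errfi1 (-1.34), Rgcc (-1.25), Sik1 (-1.15), Irs2 (-1.09), Akap12 (-0.89), Gem (-0.87), S1pr1 (-0.82), Dclre1b (-0.77), Arrdc3 (-0.66) and Cdc42ep4 (-0.54) were lower than with PBS on the log2 scale. Rassf9 (1.47), Fam84b (1.18), Fam102a (1.061), Myct1 (0.86), Tob1 (0.68) and Fry (0.57) were higher.

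If the agrin hearts held the infarction response at 1 fixed smaller share, for example through less infarcted tissue in the sample, these genes would not pass with opposite signs. In 100 simulated draws of such a share at most 2 genes did so (mean 0.07), against 18 observed, which argues against a fixed share as the whole cause of these 18 genes. Over all genes a smaller share stays open: with it simulated, 18 of 100 draws gave as many genes past in MI+Agrin against MI+PBS as the 245 observed (median 1, mean 198.4, highest 2369). Most of these draws gave few genes past between the infarcted groups, so they could seldom hold genes such as the 18, which limits the argument above. An effect of agrin on these genes may remain, as a hypothesis found and examined on the same data. The hour of collection and handling, taken up below for Nr4a1, stay open too.

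Most infarction genes had agrin estimates of the opposite sign (89.15%), with 5888 of the 6616 nearer sham with agrin than with PBS, and 1 MI+PBS library far along the axis could produce part of this. Without MI+PBS replicate 2 the share was 85.82%. It lay above the highest of 100 draws simulated for the same 11 libraries without an effect (mean 55.79%, highest 80.14%). A share above the highest draw was the prediction written beforehand for a pattern that does not rest on this library. The excess was less than the spread over splits of the group 2 and 2 (SD 5.89), a margin that the prediction did not name. With that margin required, this library's part and an effect of agrin cannot be told apart. Of the 70 assignments of the infarcted libraries, 5 gave a share as large (highest other 91.44%), so chance was not excluded. The biological explanation, a smaller response with agrin, stays open too.

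Of the immediate early and heat shock genes 4 were lower with agrin (Nr4a1, Atf3, Fosb and Btg2), as was Per1 of the clock genes, where the hour of collection, glucocorticoids or handling before freezing may differ between groups. The mean of Dbp, Per2 and Per3, which peak near Per1, differed by 0.498 (SE 0.319, exact permutation p = 0.229), and that of 16 glucocorticoid targets by -0.261 (SE 0.169, exact permutation p = 0.257), with 14 of the 16 estimates negative. The 3 that passed, Cebpb (-0.53 ± 0.09, adjusted p = 0.00983), Sgk1 (-0.67 ± 0.14, adjusted p = 0.0286) and Tsc22d3 (-0.76 ± 0.17, adjusted p = 0.0423), were lower with agrin, and Zbtb16 (1.064 ± 0.25, adjusted p = 0.0511) and Lcn2 (0.50 ± 0.28, adjusted p = 0.348) were the positive estimates. The mean of the 22 immediate early and heat shock genes differed by -0.174 (SE 0.085, exact permutation p = 0.114). That is just over 2 SE, and the requirement that the exact test pass too was added after the value was seen. With 4 animals per group these explanations and an effect of agrin cannot be told apart.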

How the results depend on the processing

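Leaving out MI+PBS replicate 2 and MI+Agrin replicate 1 together was chosen after seeing the data, and all other alternatives were planned. Of 157 named results past the threshold, 141 stayed past with the same sign under every alternative that gave a value and 16 were lost under at least 1, none with a changed sign. These were Fosb, Btg2, Nr1d1, Kcnj2, Tcap, Slc2a4, Dtna, Adamts5, Xirp1, Esam, Aldh6a1, Chac1, Myrip and Runx3 in MI+Agrin against MI+PBS, and Retnla and Postn in MI+Agrin against sham. Most of the lost calls thus lay in MI+Agrin against MI+PBS. Most of the 157 results were comparisons against sham, so the pooled counts understate how often calls between the infarcted groups were lost. The other thresholds were not applied to single named results. Named genes were chosen in part for small p-values or large changes, so these counts do not describe all 245 agrin genes. Single sham libraries (replicates 2, 3, 4 and 5) ended 6, 5, 3 and 4 of these calls, MI+PBS libraries (replicates 1, 2, 3 and 5) 7, 10, 5 and 4, and MI+Agrin libraries (replicates 1, 3, 4 and 5) 8, 9, 8 and 10.

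With at least 1 log2 unit required, 1026, 31 and 598 genes passed in MI+PBS against sham, MI+Agrin against MI+PBS and MI+Agrin against sham, and 509 were shared against sham, fewer by construction. At an adjusted p of 0.01, 1853 were shared. For MI+Agrin against MI+PBS, DESeq2 on recovered reads passed 602, edgeR 192, the fit on 8 libraries 93 and an adjusted p of 0.1 594. Without the pair of libraries named above it was 137, and without single libraries 137 to 327, with 145 without MI+PBS replicate 2 and 137 without MI+Agrin replicate 3. With the fit on 8 libraries 34.4% of its calls were higher, against 45.7%. In simulated MI+Agrin against MI+PBS data, DESeq2 called 35 of 14620 unchanged genes, against 8 by limma. It recovered 36% of 1.25-fold changes there, against 16% by limma, so it passed more genes of both kinds. Beyond this and the number of libraries used, the cause of these shifts was not tested.

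Without single libraries, MI+PBS against sham gave 5638 to 6738 genes, MI+Agrin against sham 3072 to 4707, the overlap 2704 to 3897, the share moved back 85.17% to 91.6% and the axis difference -0.262 to -0.118. Without the pair the share moved back was 80.27% and the axis difference -0.061, and with MI+PBS libraries split the share was 81.5%. With sham libraries split the overlap was 1873. With an estimated correlation, camera passed 0 lists in each comparison, and fry passed 0 in MI+Agrin against MI+PBS. A second fry test asks whether members of a list change at all, up or down. It passed 13 lists there, against 30 in MI+PBS against sham and 26 in MI+Agrin against sham. Of these, only the fetal and stress, branched-chain amino acid, myofibroblast, and glycolysis and hypoxia lists also passed camera at the preset correlation. The others include the immediate early list (adjusted p = 6.79e-06 by this fry test) and the endothelial list (adjusted p = 3.79e-05 by this fry test). The agrin receptor list (adjusted p = 0.00247 by this fry test) and the YAP and TEAD list (adjusted p = 0.0211 by this fry test) were also among them.

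The replicate number as a block gave 75 genes for MI+Agrin against MI+PBS, 5727 for MI+PBS against sham and 3660 for MI+Agrin against sham. Deviations of libraries with the same number correlated at -0.285 to 0.121, and none correlated best with its own number. This gave no sign of pairing, but cannot exclude a shared litter, batch or day, and the labels do not state what the numbers mean. The block ended 13 of the 157 named calls.

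Estimates that did not pass changed sign for Agrn in MI+Agrin against MI+PBS, to 0.0019 with TMM, 0.0079 with edgeR and 0.0072 with DESeq2. Leaving out MI+PBS replicate 3 or 5 gave 0.0546 and 0.005, and MI+Agrin replicate 3, 4 or 5 gave 0.0724, 0.0183 and 0.0049, in a range of -0.0993 to 0.0724 over single libraries. Myh7 in MI+Agrin against sham was 0.0049 without sham replicate 4 (range -0.2514 to 0.0049), and in MI+Agrin against MI+PBS -0.0591 without the pair. Nppa in MI+Agrin against MI+PBS was 0.0542 without MI+PBS replicate 2 (range -0.5006 to 0.0542). The cause was not tested. Alternatives written for count tables (relative log expression and upper-quartile scaling, voom, filterByExpr) and the authors' own comparison were not run. In simulated MI+Agrin against MI+PBS data, limma recovered 16% of 1.25-fold changes in genes with a mean of at least 50. Small changes were thus mostly missed at this number of animals.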

Other observations

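The counts over other groupings of the libraries were chosen as tests only after the results were seen. Genes outside the infarction response made up 43 of the 245 agrin genes, and 97 of the 245 also passed against sham. Per1 is among these, as it fell with agrin against both PBS and sham and did not pass in MI+PBS against sham (0.20 ± 0.22, adjusted p = 0.479).

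Among glucocorticoid targets, chosen after values were seen, changes against sham varied from gene to gene, and their mean did not pass between the infarcted groups (-0.261, exact permutation p = 0.257). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose against sham with PBS (2.08 ± 0.20) and with agrin (2.05 ± 0.20). Zbtb16 rose by 1.62 ± 0.25 and 2.69 ± 0.25 and did not pass between the infarcted groups (adjusted p = 0.0511). Cebpb rose with PBS only (0.63 ± 0.09 and 0.09 ± 0.09, adjusted p = 0.000185 and 0.462), with a difference between the infarcted groups of -0.53 ± 0.09 (adjusted p = 0.00983). Dbp and Hlf, output genes of the clock, fell with PBS (-1.44 ± 0.27 and -1.09 ± 0.25) and did not pass with agrin (-0.42 ± 0.27 and -0.50 ± 0.25), and neither passed between the infarcted groups (1.03 ± 0.27 and 0.59 ± 0.25).

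The counts of genes were highest in the real split in all 3 comparisons, so chance was excluded only as far as 35 splits allow. In each, 1 of the 35 splits of the 8 libraries gave as many, the real one, with 6616 genes against at most 1 in any other split for MI+PBS against sham, 245 against 3 for MI+Agrin against MI+PBS and 4261 against 1 for MI+Agrin against sham. For 17 lists in MI+PBS against sham, 15 of 35 splits gave as many (highest other 23). For 19 lists in MI+Agrin against sham, 9 did (highest other 25). In both, the highest other split kept 3 libraries of each group together, and so part of the real difference. Such splits cannot tell whether chance gives as many lists against sham. For 13 lists in MI+Agrin against MI+PBS, 17 did, and chance was not excluded. The highest other there was 20, with 2 libraries of each group on each side. For the overlap of 3719 genes, 2 of 100 drawn assignments gave as many, the real one among them. The highest other was 3825, in a draw that kept the 4 sham libraries together. These draws therefore show that sham differs from the infarcted hearts, and do not test an overlap beyond that.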
